A study of Mus musculus with 16 samples.

How the data were processed

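Small RNA libraries from WT and p73 KO mouse tracheal epithelial cultures at days 0, 4, 7 and 14 were analysed from the deposited table of 1269 small RNAs (677 miRNAs, 279 small nucleolar RNAs, 185 piRNAs, 71 ribosomal RNAs, 50 small nuclear RNAs and 7 unnamed predicted miRNA rows). Per the labels, RNA was extracted with a column kit and libraries were prepared with a TruSeq RNA kit. The submitters' processing notes name mm10 and DESeq2 without a version; aligner, annotation and counting are not given in the sources used here. The deposited table is headed as read counts, but its values were a normalised signal. Whole reads were recovered as multiples of 1 step per library (tolerance 0.0055 in deposited units), found for each library by a search between 0.3 and 2.2. At days 0 and 4, the inverse of each step equalled the DESeq2 size factor computed within that day. At days 7 and 14 the low rows were blank, so the step is less certain. The deposited table of comparisons gave log2 fold changes and, per the file headers, an adjusted p-value for KO over WT at each day, made by the authors.

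Because the days had been normalised separately, the values of each day were moved by 1 log2 shift (-0.246, -0.178, 0.42 and 0.047 at days 0, 4, 7 and 14), from the 287 rows used for it, before days were compared. Comparisons of KO with WT within a day hold the deposited values, and all other levels hold the shifted ones, so a level of 1 small RNA differs between them. Values were present for 1234 rows at day 0, 805 at day 4, 326 at day 7 and 309 at day 14, and for 298 rows at every day. 5 predicted rows had the values of a named miRNA (miR-151-3p, miR-125a-5p, miR-378a-3p, miR-183-5p and miR-1198-5p) and were left out. Over the remaining rows the libraries held 197497 to 1777273 reads. PCR reads without molecular identifiers are not independent molecules, and counting error alone understates their spread.

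The groups, alternatives, lists and the rule for naming small RNAs were fixed before the data were examined. The planned test was edgeR on counts. Since the values were not counts, the stated fallback was used: limma 3.58.1 in R 4.3.3 on the log2 of the value plus 1, with the variance trend and all 16 libraries in 1 fit of 8 groups, and 14.5 degrees of freedom after shrinkage. The pseudocount of 1 and the filter, a value of at least 10 in at least 2 of the 4 libraries of each day compared, were chosen once the unit was known. Adjusted p are Benjamini-Hochberg values over the small RNAs tested, with a threshold of 0.05. The tests were KO against WT at each day and averaged over days, each day against day 0 within genotype, the interaction of genotype and day, and a genotype difference at any day. 22 lists of miRNAs were tested with camera (preset correlation 0.01, then an estimated one) where at least 3 rows were measured, adjusted over the lists of a comparison; RNA classes were compared the same way. The p53 target list shares miR-34a, miR-34b and miR-34c with the miR-34 and miR-449 list, miR-141 and miR-200c with the miR-200 list, miR-15a and miR-16 with the miR-15/16 list, and miR-143 and miR-145a with the mesenchymal list.

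Named small RNAs were the 10 largest rises and 10 largest falls past the threshold with a mean of at least 10 and no overlap of the libraries, the 5 smallest p where fewer than 3 passed, every miR-34 and miR-449 row of the KO against WT and day 14 comparisons, and the 5 most abundant. Positions are mm10, counted from 1, with genes from the reference annotation. The labels call the 2 libraries of a group independent biological replicates. Whether replicate numbers pair them was checked by correlating the difference between replicates across groups over small RNAs: r was -0.31 to 0.13 between genotypes (16 pairs), 0.08 to 0.28 within WT (6 pairs) and 0.3 to 0.47 within KO (6 pairs), so a blocked count is given where it differed by more than 1.5 times, beside the KO time course and beside the interaction, which holds the same KO libraries. The WT time course counts also rose by more than 1.5 times with that block. They are given with the other alternatives. Replicates within a group correlated at r = 0.939 to 0.983 across small RNAs, which are not independent replicates.

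The test was tried on simulated data: with a 2-fold change it recovered 19.8% of changed rows at day 0 and 19.2% at day 14, and with a 4-fold change 79.1% and 85.9%, while 7 of 1430 and 0 of 1318 unchanged rows were called. The simulation used 1 dispersion for all rows (0.086), independent libraries and known size factors. The real libraries differ in this, so the rates hold for the simulated setting only. The alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, DESeq2 size factors, upper-quartile factors and library totals (these 3 planned in edgeR and run in limma), no filter, a filter of 10 CPM, robust shrinkage, replicate blocks, the 4 libraries of a comparison alone, a threshold of 0.1, fry, an estimated correlation and leaving out each library. Added after the values were seen were edgeR 4.0.16 quasi-likelihood, TMM factors, pseudocounts of 0.5 and 5, a minimum value of 50, identical rows kept, factors from miRNAs, miRNA rows only and, for genotype over all days, libraries of 1 genotype and replicate number taken as correlated or averaged. DESeq2, limma-voom and edgeR used the recovered reads. Other ways of grouping the libraries were counted over 100 splits drawn from the 648 possible within days.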

Results

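Small RNA was measured in primary mouse tracheal epithelial cells grown at an air-liquid interface, a culture in which a basal cell layer forms multiciliated cells once its surface is exposed to air. Cultures from wild-type mice (WT) and from mice lacking p73 in the whole animal (KO) were taken at days 0, 4, 7 and 14, with 2 libraries per genotype and day and 16 libraries in all. p73 is a transcription factor of the p53 family with a known role in multiciliated cells. The libraries held between 197497 reads (WT day 0 replicate 2) and 1777273 reads (WT day 14 replicate 2), as recovered from the deposited normalised values. These counts rest on a search for the step of 1 read, which is less certain at days 7 and 14. The p73 transcript is not a small RNA and is not among the features measured, so the knockout could not be checked here.

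MicroRNAs made up 92.5% to 97.1% of the summed values of each library. The most abundant was miR-92b-3p, which shares its seed with the proliferation-linked miR-92a, with a mean share of 29.15% over all libraries. At day 0 it held 1.11% to 2.3%, less than each of the 4 that follow. Next by mean share were miR-125a-5p with 8.08%, miR-92a-3p with 7.7%, miR-99b-5p with 5.67% and miR-191-5p with 5.09%. All values below are normalised read counts with the SD and n = 2 per group.

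The WT time course shows which small RNAs accompany differentiation. By day 14 the multiciliated cell miRNA miR-449a-5p, in an intron of Cdc20b on chromosome 13 (113037549 to 113037570), had risen from 7.75 ± 8.93 to 4340 ± 1100, a log2 fold change of 9.4 (SE 0.59, adjusted p = 3.41e-08). The day 0 libraries held 7 reads and 1 read of it. miR-92b-3p (chromosome 3, 89227126 to 89227147) rose from 7530 ± 1300 to 391000 ± 57000 (log2 5.7, adjusted p = 1.06e-07). miR-375-3p (chromosome 1, 74900661 to 74900682), known from neuroendocrine and secretory cells, rose from 319 ± 22.5 to 7900 ± 46.2 (log2 4.63, adjusted p = 5.51e-07). miR-34c-5p, which shares its seed with miR-449a, rose from 1010 ± 111 to 3530 (libraries 3870 and 3180; log2 1.81, adjusted p = 0.00018). miR-34b-3p, encoded next to it, rose from 147 ± 11.9 to 353 ± 63.8 (log2 1.25, adjusted p = 0.0161). Not past the threshold in limma were miR-34c-3p, at 42.2 ± 11.5 and 93.8 ± 7.99 (adjusted p = 0.0894), and miR-34a-5p, at 40.2 ± 14.1 and 47.9 ± 7.36 (adjusted p = 0.718). Both arms of miR-210, the hypoxia-induced miRNA, fell: the 5p arm from 802 ± 188 to 50.4 ± 3.94 (log2 -3.95) and the 3p arm from 1290 ± 18.3 to 149 ± 4.14 (log2 -3.11). miR-125b-1-3p fell from 180 ± 1.79 to 21.1 ± 3.18 (log2 -3.04), miR-351-5p from 219 and 168 in the day 0 libraries to 25.8 ± 7.18 (log2 -2.88) and miR-99b-3p by log2 -1.61. Smaller rises were those of miR-378a-5p, miR-872-3p (in an intron of the ciliary transport gene Ift74), miR-425-3p, miR-1947-5p, miR-339-3p and Snord85, at log2 1.69 to 2.21. Smaller falls were those of miR-504-5p, miR-100-5p, miR-1981-5p, Snora52 and miR-31-5p, a miRNA of stratified epithelium, at log2 -2.05 to -1.59. Of 279 small RNAs tested at day 14 in limma, 17 rose and 21 fell at an adjusted p under 0.05. More passed with replicate number as a block within genotype. Of the 5 measured miR-34 and miR-449 rows, 3 passed over all small RNAs and 4 adjusted over the list alone, with a median log2 of 1.25. The list ranked higher than the rest in camera (adjusted p = 0.00054), which was lost at adjusted p = 0.0612 with an estimated correlation. Without WT day 14 replicate 2, 16 passed and without replicate 3, 15 passed. miR-34b-3p and each of the smaller rises and falls named lost its call without one of them (adjusted p 0.052 to 0.157). Without WT day 0 replicate 2 or replicate 3, the log2 was 10.67 or 8.13 for miR-449a-5p, 1.36 or 3.07 for miR-378a-5p, 2.82 or 1.17 for miR-425-3p and -2.88 or -1.22 for miR-504-5p, and the smaller of each but that of miR-449a-5p did not pass. Scaling to library totals moved the median log2 of all small RNAs to -1.11 and called 139, of which 4 rose. Library totals include miR-92b-3p, at 1.67% and 2.3% of the values of the day 0 libraries and 55.07% and 47.3% at day 14. Its rise lowers the share of all other small RNAs, so these falls do not show a general decline. Of the calls, 25 of 45 rose with TMM factors and 26 of 43 with factors from miRNAs.

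miR-449a-5p, miR-92b-3p and miR-375-3p had also risen at the earlier WT days. miR-449a-5p had reached 1840 at day 4 (libraries 2150 and 1520; log2 8.16, adjusted p = 2.63e-07) and 3520 ± 470 at day 7 (log2 9.12, adjusted p = 5.55e-08). miR-92b-3p had reached 150000 ± 44600 and then 262000 ± 57000 (log2 4.3 and 5.12), and miR-375-3p 1720 ± 84.9 and then 4350 ± 1620 (log2 2.43 and 3.71), all past the threshold. At day 4, miR-8112 (log2 -2.64), miR-351-5p (-2.05), miR-210-5p (-2.02), miR-125b-1-3p (-1.56) and miR-106b-3p (-1.07) fell. At day 7, miR-210-5p (log2 -3.2), miR-351-5p (-2.96) and miR-125b-1-3p (-2.22) were lower still than at day 0. The small nucleolar RNA Gm26205, inside an exon of the ribosomal protein gene Rpl6 on chromosome 5 (121205010 to 121205143), rose from 12.5 ± 0.637 to 288 ± 32.6 at day 7 (log2 4.4, adjusted p = 0.000338). That exon is annotated as neither coding nor UTR. Other rises at day 7 were those of miR-425-3p, miR-872-3p, miR-99a-5p, the epithelial miR-200a-3p, the piRNA-annotated DQ714439 and miR-30b-5p, at log2 1.16 to 2.1. Other falls were those of miR-127-3p of the imprinted Dlk1-Dio3 cluster, miR-193b-3p, miR-504-5p, miR-210-3p, miR-1981-5p, miR-99b-3p and miR-326-3p, at log2 -2.74 to -1.56. At day 4, 3 rose and 5 fell of 312 tested, and at day 7, 10 rose and 13 fell. With replicate number as a block within genotype, more passed at both days. The miR-34 and miR-449 list ranked higher than the rest at day 7 (adjusted p = 0.0425, or adjusted p = 0.354 with an estimated correlation). The day 4 count was 21 without WT day 0 replicate 2, 5 without WT day 0 replicate 3 and 4 without WT day 4 replicate 3. The day 4 falls each lost their call without WT day 4 replicate 2 or 3 (adjusted p 0.0518 to 0.183), and library totals called 18, of which 3 rose. The day 7 count was 8 without WT day 7 replicate 2, which ended the call of each of the other rises and falls but miR-99b-3p (adjusted p 0.0557 to 0.25), and 11 without replicate 3. Without WT day 0 replicate 2 or replicate 3, the log2 of miR-449a-5p was 9.43 or 6.89 at day 4 and 10.39 or 7.84 at day 7. At day 7 it was then 2.93 or 1.28 for miR-425-3p, -2.07 or -3.41 for miR-127-3p, -2.73 or -1.07 for miR-504-5p and -2.25 or -0.86 for miR-326-3p, the smaller of each not past the threshold. Without replicate 2 or 3 of the later day it was 1.48 or 2.73 for miR-425-3p at day 7 and -3.24 or -2.03 for miR-8112 at day 4. Library totals called 115, of which 4 rose, at a median log2 of -0.88. At day 7 miR-92b-3p held 37.08% and 43.8% of the values of the WT libraries, which lowers the share of the others.

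KO cultures were examined over the same days. The multiciliated cell miRNA miR-449a-5p rose in KO too, from 20.5 ± 10.6 at day 0 to 3900 and 3600 in the day 14 libraries (log2 7.53, adjusted p = 3.51e-07). miR-92b-3p rose from 6030 ± 981 to 291000 ± 12800 (log2 5.6, adjusted p = 2.69e-07) and miR-375-3p from 279 ± 183 to 4810 ± 834 (log2 4.26, adjusted p = 1.62e-06). miR-34c-5p was at 1080 ± 118 at day 0 and 1130 ± 78.6 at day 14 (log2 0.07, adjusted p = 0.861), and miR-34b-3p at 150 ± 2.04 and 100 ± 23.4 (log2 -0.59, adjusted p = 0.189). miR-34c-3p had a log2 of -1.08, which did not pass, and scaling to library totals called it and miR-34b-3p lower (adjusted p = 0.0166 and 0.0243). miR-34a-5p was at 40.9 ± 26.1 at day 0 and 32.6 ± 4.34 at day 14 (adjusted p = 0.806 in limma). The largest falls were those of miR-100-5p, from 209 ± 100 to 8.52 ± 0.684 (log2 -4.39), and the hypoxia-induced miR-210-3p, from 1150 ± 356 to 86.9 ± 28.1 (log2 -3.72), both at adjusted p = 2.88e-05. miR-326-3p, miR-504-5p, miR-455-3p, miR-221-5p, miR-125b-1-3p, miR-15b-5p, miR-99b-5p and miR-702-3p fell by log2 -2.66 to -2.18. Among the further rises were small nuclear and nucleolar RNAs, Gm24265 (log2 2.95), Gm24134 (2.16), Gm23262 (2.1), Snora68 (2) and Gm25506 (1.91), with the piRNA-annotated DQ726397 (2.05) and miR-671-3p (2.02). Of 279 small RNAs, 34 rose and 46 fell in limma. Of the 9 measured rows of the miR-99, miR-100 and miR-125 family, 4 fell, with a median log2 of -1.13, and the family ranked lower than the rest (adjusted p = 0.0037, or adjusted p = 0.57 with an estimated correlation). As a class, miRNAs ranked lower than the other small RNAs (median log2 -0.51, camera adjusted p = 3.2e-08, or adjusted p = 0.0235 with an estimated correlation). Small nucleolar RNAs ranked higher (median log2 0.36, camera adjusted p = 9.2e-06, or adjusted p = 0.0711 with an estimated correlation). Camera ranks rows, not class totals. miRNAs made up 93.7% and 92.7% of the values of the KO libraries at day 0 and 96.3% and 95.6% at day 14. Leaving out a library gave 48 (KO day 0 replicate 2), 37 (day 0 replicate 3), 42 (day 14 replicate 2) or 22 (day 14 replicate 3). Without KO day 0 replicate 2 Gm24265, Gm23262, DQ726397, Snora68, miR-455-3p, miR-221-5p and miR-99b-5p lost their calls (adjusted p 0.0557 to 0.226). Without KO day 0 replicate 2 or replicate 3, the log2 was 4.98 or 3.54 for miR-375-3p and -3.21 or -1.98 for miR-504-5p. Without KO day 14 replicate 2 or replicate 3, it was 1.08 or 3.02 for DQ726397 and -3.48 or -1.55 for miR-455-3p, the smaller of each not past the threshold. The share that rose depended on scaling: 53 of 73 with factors from miRNAs, 39 of 74 with upper-quartile factors and 15 of 91 with library totals, at median log2 of 0.46, 0.17 and -0.39.

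At day 4 in KO, miR-449a-5p reached 1860 (libraries 1470 and 2240; log2 6.48), miR-92b-3p 98900 ± 60800 (3.89) and miR-375-3p 1260 ± 103 (2.33), and DQ714439 rose by log2 1.28. miR-100-5p (log2 -2.35), miR-874-3p (-1.96), miR-351-5p (-1.92), miR-125b-1-3p (-1.64), miR-210-5p (-1.6), miR-28a-3p (-1.32) and miR-99b-3p (-1.16) fell. At day 7, miR-449a-5p reached 3600 ± 158 (log2 7.47), miR-92b-3p 226000 ± 1520 (5.24) and miR-375-3p 3510 (libraries 3390 and 3640; 3.82). miR-100-5p (log2 -3.33), miR-210-3p (-2.45), miR-127-3p (-2.43), miR-210-5p (-2.35), miR-702-3p, miR-326-3p, miR-351-5p, miR-700-5p, miR-125b-1-3p and miR-504-5p (-1.74) fell. Gm24134, DQ714439, miR-671-3p, Gm25506, an unnamed predicted miRNA on chromosome 6 (124717981 to 124717998) and Snord57 rose by log2 1.31 to 1.69. At day 4, 4 rose and 7 fell of 312, and at day 7, 9 rose and 21 fell. With replicate number as a block within genotype, which the KO libraries followed, 17 passed at day 4 and 49 at day 7. The miR-99, miR-100 and miR-125 family ranked lower at day 4 (3 of 9 fell, adjusted p = 0.0498) and day 7 (4 of 9 fell, adjusted p = 0.007), or at adjusted p = 0.587 and p = 0.664 with an estimated correlation. As a class, miRNAs ranked lower at days 4 and 7 (median log2 -0.36 and -0.46, camera adjusted p = 2.85e-05 and 2.67e-05). Small nucleolar RNAs ranked higher (median log2 0.15 and 0.12, camera adjusted p = 0.000758 and 0.000363). With an estimated correlation the calls were lost for miRNAs (adjusted p = 0.0735 and 0.093) and small nucleolar RNAs (0.186 and 0.172). The day 4 count was 5 without KO day 0 replicate 2 or replicate 3, 18 without KO day 4 replicate 2 and 4 without KO day 4 replicate 3. The last ended the call of DQ714439 and of each fall but miR-874-3p (adjusted p 0.0856 to 0.165), itself lost without KO day 0 replicate 3 (adjusted p = 0.163). Without KO day 4 replicate 2 or replicate 3, the day 4 log2 was 4.57 or 3.22 for miR-92b-3p and -3.11 or -1.59 for miR-100-5p. Without KO day 0 replicate 2 or replicate 3, it was 3.05 or 1.62 for miR-375-3p at day 4 and, at day 7, 4.54 or 3.1 for miR-375-3p, -3.35 or -1.51 for miR-127-3p and -2.35 or -1.12 for miR-504-5p, the last 2 not past the threshold at the smaller value. Without KO day 7 replicate 2 or replicate 3, it was -4.04 or -2.62 for miR-100-5p and -3.19 or -1.71 for miR-210-3p. The day 7 count was 9 without KO day 0 replicate 3 and 8 without KO day 7 replicate 3. The last left no call for miR-210-3p, miR-127-3p, miR-702-3p, miR-326-3p, miR-351-5p, miR-700-5p, miR-504-5p and the smaller rises but DQ714439 (adjusted p 0.0599 to 0.225), and 18 of 29 rose with factors from miRNAs, 9 of 22 with upper-quartile factors and 7 of 58 with library totals.

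Comparing KO with WT at each day asks which small RNAs depend on p73. At day 0, none of the 5 measured rows of the multiciliated family passed the test. miR-34c-5p stood at 849 ± 93.4 in WT and 911 ± 99.2 in KO (log2 0.1, 95% interval -0.44 to 0.64), and miR-34b-3p had a log2 of 0.03 (95% interval -0.65 to 0.71). miR-34c-3p had a log2 of -0.12 and miR-34a-5p of -0.09. The smallest p belonged to 3 small nucleolar RNAs, Gm23969 (log2 -1.17), Gm25894 (1.34) and Snord37 (1.88), each at adjusted p = 0.343, followed by miR-99a-5p (1.27, adjusted p = 0.375) and miR-449a-5p (1.69, adjusted p = 0.581; 6.54 ± 7.53 and 17.3 ± 8.97). Of 342 small RNAs, limma called 0, with 25 at an unadjusted p under 0.05; edgeR, limma-voom and DESeq2 called 0 each. The miR-99, miR-100 and miR-125 family had 9 measured rows, none called, with a median log2 of 0.8, and ranked higher in KO (adjusted p = 0.0458, or adjusted p = 0.668 with an estimated correlation). As a class, miRNAs ranked higher in KO, with 121 of 196 higher (median log2 0.14, camera adjusted p = 0.0175). Small nucleolar RNAs ranked lower (median log2 -0.19, camera adjusted p = 0.0126). Both class calls were lost at adjusted p = 0.275 with an estimated correlation. Without WT day 0 replicate 2, 7 passed, among them miR-99a-5p (adjusted p = 0.0359) and miR-449a-5p (adjusted p = 0.000353), which also passed with no filter on low values (adjusted p = 0.00228). The log2 of miR-449a-5p was 2.96 without that library and 0.42 without WT day 0 replicate 3 (adjusted p = 0.896).

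At day 4, Snord73a, a small nucleolar RNA in an intron of the ribosomal protein gene Rps3a1 (chromosome 3, 86138791 to 86138858), was higher in KO, at 69.4 ± 20.6 against 11.2 ± 1.85 in WT (log2 2.51, SE 0.38, adjusted p = 0.00696). miR-34b-3p stood at 61.6 ± 13.9 in KO and 124 ± 8.06 in WT (log2 -1.02, adjusted p = 0.701), and miR-672-5p at 587 ± 248 and 1130 ± 228 (log2 -1, adjusted p = 0.701). miR-184-3p, a miRNA of stratified epithelium, had a log2 of 2.1 (adjusted p = 0.78) and Snord93 of 1.4 (adjusted p = 0.792). Of the 7 miR-34 and miR-449 rows, 0 passed over all small RNAs and 1, lower in KO, adjusted over the list alone. The others were miR-34c-5p -0.32, miR-34c-3p 0.14, miR-34b-5p -0.51, miR-34a-5p 0.49, miR-449a-5p 0.01 and miR-449c-5p 0.02 on the log2 scale (adjusted p = 0.998 each). Snord73a was the 1 call among 340 small RNAs in limma, with 14 at an unadjusted p under 0.05. The basal and stratified epithelial list, 5 rows with none called and a median log2 of 0.47, ranked higher in KO (adjusted p = 0.0356, or adjusted p = 0.601 with an estimated correlation). As a class, ribosomal RNA ranked higher in KO, with 12 of 16 higher (median log2 0.33, adjusted p = 0.021, or adjusted p = 0.307 with an estimated correlation). The miRNAs ranked lower at the same camera values (median log2 -0.07, adjusted p = 0.021, or adjusted p = 0.307 with an estimated correlation). The Snord73a call was lost without WT day 4 replicate 2 (adjusted p = 0.0533), WT day 4 replicate 3 (0.123) or KO day 4 replicate 2 (0.0789). It was also lost in DESeq2 (adjusted p = 0.0527), edgeR (0.146), limma-voom (0.29), with the 4 libraries of the day alone (0.106) and with a minimum value of 50 (0.296).

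At day 7, miR-34b-3p (chromosome 9, 51103574 to 51103595) was lower in KO, at 84.6 ± 15 against 277 ± 95.7 in WT (log2 -1.67, SE 0.32, adjusted p = 0.0358). Its neighbours stood at 1220 ± 116 and 2360 ± 437 for miR-34c-5p (log2 -0.94, adjusted p = 0.164) and at 29.5 ± 8.12 and 79.8 ± 29.9 for miR-34c-3p (log2 -1.38, adjusted p = 0.423). miR-449a-5p was at 4820 ± 211 in KO and 4710 ± 629 in WT (log2 0.04, 95% interval -1.21 to 1.29), miR-449c-5p at 11800 ± 4500 and 11500 (WT libraries 11900 and 11100; log2 -0.02, 95% interval -0.86 to 0.82). miR-34a-5p was at 42.2 ± 1.52 and 45.7 ± 0.969 (log2 -0.11). Gm26205 was at 51.9 ± 31.6 in KO and 385 ± 43.6 in WT (log2 -3, adjusted p = 0.0534), and miR-351-5p had a log2 of 1.61 (95% interval 0.72 to 2.49, adjusted p = 0.164). Of 321 small RNAs limma called 1, with 18 at an unadjusted p under 0.05. The miR-34 and miR-449 list, 6 rows with 1 called over all small RNAs, 3 adjusted over the list alone and a median log2 of -0.53, ranked lower in KO (adjusted p = 0.00279, or adjusted p = 0.0628 with an estimated correlation). So did the reported p53 family targets, 11 rows of which the same row was called (adjusted p = 0.00361, or adjusted p = 0.205 with an estimated correlation). The epithelial miR-200 family, 8 rows with none called, which shares miR-141 and miR-200c with the p53 target list, also ranked lower (adjusted p = 0.0428, or adjusted p = 0.64 with an estimated correlation). As a class, miRNAs ranked lower in KO (median log2 -0.12, camera adjusted p = 0.00274) and small nucleolar RNAs higher (0.11, camera adjusted p = 0.011). Both class calls were lost at adjusted p = 0.302 with an estimated correlation. The miR-34b-3p call was lost without WT day 7 replicate 3 (adjusted p = 0.651), KO day 7 replicate 2 (0.178) or KO day 7 replicate 3 (0.0547). It was also lost in edgeR (0.186), limma-voom (0.165), with upper-quartile factors (0.0517), library totals (0.0699) or the 4 libraries alone (0.291). Gm26205 passed in 8 of its 21 alternatives, DESeq2 and limma-voom among them (adjusted p 1.38e-08 to 0.651), and miR-351-5p in 2, no filter and factors from miRNAs; the latter called 3 small RNAs, of which 1 was higher in KO.

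At day 14, mature arms of miR-34b and miR-34c were lower in KO. miR-34c-5p (chromosome 9, 51103076 to 51103098, in an intron of Btg4 on the opposite strand) stood at 1170 ± 81.2 in KO against 3640 ± 503 in WT (log2 -1.63, SE 0.25, adjusted p = 0.00365). miR-34b-3p was at 104 ± 24.2 against 364 ± 65.9 (log2 -1.81, SE 0.32, adjusted p = 0.00754) and miR-34c-3p (51103044 to 51103065) at 18.5 ± 3.95 against 96.9 ± 8.26 (log2 -2.34, SE 0.43, adjusted p = 0.00859). miR-449c-5p (chromosome 13, 113036008 to 113036028) stood at 4890 ± 58.6 in KO and at 5970 and 6160 in the WT libraries (log2 -0.31, 95% interval -1.15 to 0.53, adjusted p = 0.676; 0.06 under library totals). miR-449a-5p was at 3880 ± 221 and 4480 ± 1140 (log2 -0.19, 95% interval -1.44 to 1.07, adjusted p = 0.885; 0.18 under library totals and 0.03 with factors from miRNAs). miR-34b-5p had a log2 of -1.68 (adjusted p = 0.0991; 0.0242 in limma-voom and 0.0204 in edgeR) and miR-34a-5p of -0.54 (adjusted p = 0.55). Of the 7 measured miR-34 and miR-449 rows, 3 were lower over all small RNAs and 4 adjusted over the list alone, with a median log2 of -1.63. The list ranked lower in KO (adjusted p = 0.000136, or adjusted p = 0.0548 with an estimated correlation). The reported p53 family targets, with the same 3 rows lower of 11, had a median log2 of -0.54 (adjusted p = 0.00171, or adjusted p = 0.374 with an estimated correlation).

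Outside that family, miR-455-3p, in an intron of the collagen gene Col27a1 on chromosome 4, was lower in KO at day 14, at 8.03 ± 7.44 against 115 ± 80.9 in WT (log2 -3.77, SE 0.88). miR-874-3p, in an intron of Klhl3, was at 36.2 ± 10.8 against 138 ± 45.5 (log2 -1.89), and miR-324-5p, in a UTR exon of the Wnt signalling gene Dvl2, at 20.2 ± 4.09 against 59.6 ± 8.35 (log2 -1.52). Higher in KO were n-R5s209, a copy of 5S ribosomal RNA, at a mean of 398 against 116 ± 26.7 (log2 1.76, SE 0.41), and Rnu3a, the U3 small nucleolar RNA needed to process ribosomal RNA, at 130 ± 29.3 against 37.7 ± 23.3 (log2 1.88, adjusted p = 0.034). Snord73a was at 45.8 ± 8.34 against 13.7 ± 0.686 (log2 1.66), miR-125b-1-3p at 66.4 ± 16.9 against 21.8 ± 3.28 (log2 1.55), and miR-351-5p at 86.7 ± 39 against 26.6 ± 7.42 (log2 1.62, adjusted p = 0.0415). The adjusted p of the other 6 was 0.0276. As a class, 14 of 15 ribosomal RNA rows had a higher mean in KO, with a median log2 of 1.13, against a median of 1.08 for 4 small nuclear RNAs, all higher, 0.21 for small nucleolar RNAs and -0.19 for miRNAs. Of the 15, 1 was called over all small RNAs and 5 adjusted over the class alone. The class ranked higher in KO in camera (adjusted p = 2.99e-06), which was lost at adjusted p = 0.0534 with an estimated correlation. In camera miRNAs ranked lower (adjusted p = 1.74e-06) and small nucleolar RNAs higher (adjusted p = 0.00281). With an estimated correlation these were lost too (adjusted p = 0.0534 and 0.273). For 1 direction, fry gave an unadjusted p = 0.00147 for ribosomal RNA, 0.0858 for miRNAs and 0.183 for small nucleolar RNAs. Ribosomal RNA made up 0.35% and 0.55% of the values of the KO libraries and 0.15% and 0.13% of the WT libraries of day 14, a log2 ratio of 1.65 (95% interval 0.98 to 2.32 from the SD pooled over the 8 groups). In all, limma called 11 of 304 small RNAs, 5 higher and 6 lower in KO, with 57 at an unadjusted p under 0.05. DESeq2 called 36, edgeR 54, limma-voom 56 and limma on the 4 libraries of the day 45. Single libraries moved the count: 7 passed without WT day 14 replicate 2, 1 without WT replicate 3, 4 without KO replicate 2 and 0 without KO replicate 3. miR-34c-5p kept its call except without KO replicate 3 (adjusted p = 0.0513), miR-34b-3p and miR-34c-3p lost theirs without it (0.0847) or without WT replicate 3 (0.143), and the 8 others lost theirs without WT replicate 3 (0.203 to 0.466). The log2 of miR-455-3p was -4.56 without WT replicate 2, -2.99 without WT replicate 3, -4.74 without KO replicate 2 and -2.81 without KO replicate 3, and that of Rnu3a was 2.54 and 1.23 without the WT libraries in that order. Library totals moved the median log2 of all small RNAs to 0.34 and called 26, of which 21 were higher. Factors from miRNAs moved it to 0.19 and called 13, of which 8 were higher, and miR-324-5p was lost under both (adjusted p = 0.0807 and 0.0567).

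**Figure D1:**
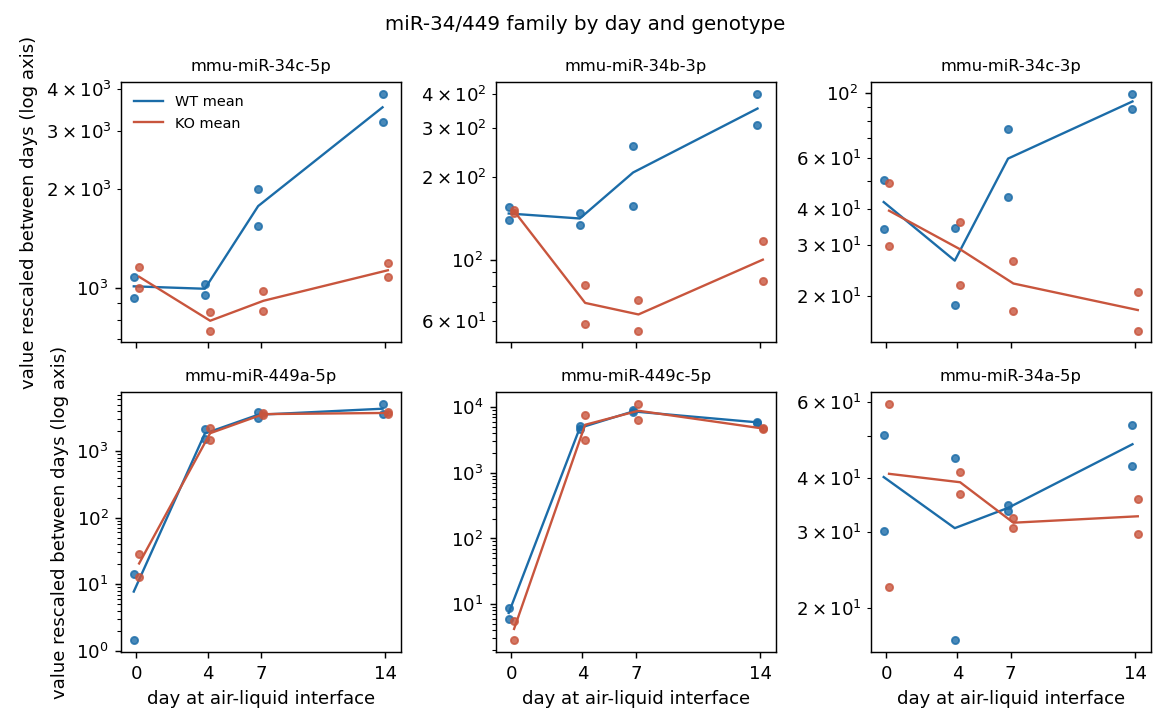
Normalised read counts rescaled between days (log axis) of 6 members of the miR-34 and miR-449 family against day at the air-liquid interface, with points for the 2 libraries of each genotype and lines for their means. miR-34c-5p reached 3530 in WT and 1130 in KO at day 14.

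**Figure D2:**
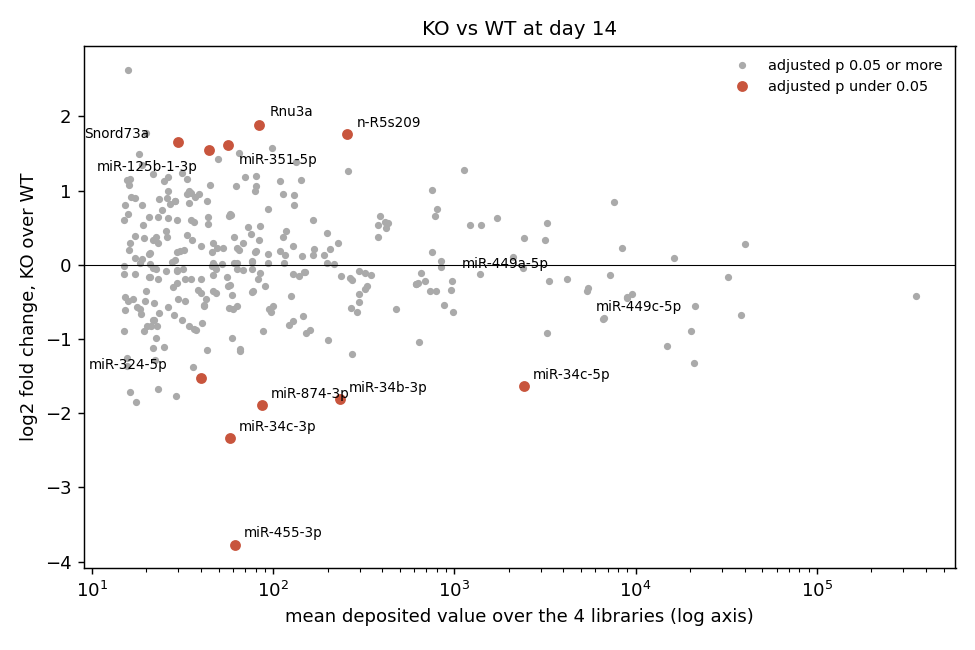
Log2 fold change of KO over WT at day 14 against the mean normalised read count of the 4 libraries (log axis), 1 point for each of 304 small RNAs, with the 11 past the threshold coloured. miR-34c-5p, miR-34b-3p and miR-34c-3p lie at -1.63, -1.81 and -2.34.

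**Figure D3:**
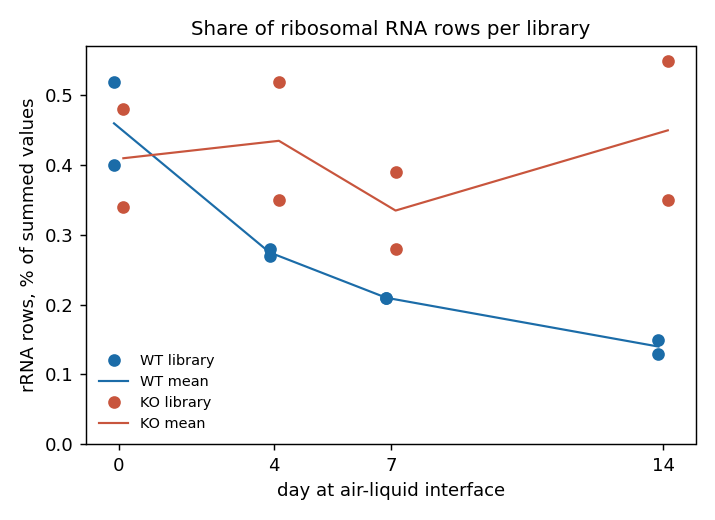
Share of ribosomal RNA in the summed values of each library (percent) against day, with points for libraries and lines for the mean of each genotype. At day 14 the KO libraries sit at 0.35% and 0.55% and the WT libraries at 0.15% and 0.13%.

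Averaged over the 4 days, miR-34b-3p (log2 -1.12, SE 0.16, adjusted p = 0.00137), miR-34c-5p (-0.7, adjusted p = 0.00421), miR-34c-3p (-0.92, adjusted p = 0.0294) and miR-672-5p (-0.71, adjusted p = 0.0185) were lower in KO. miR-125b-1-3p (log2 1.02, adjusted p = 0.00295), miR-351-5p (1.23, adjusted p = 0.00295), the stratified epithelial miR-31-5p (0.79, adjusted p = 0.0185) and the ribosomal RNA Gm25164 (1.04, adjusted p = 0.0496) were higher. miR-31-5p stood at 2420 ± 273 in KO and at 1710 and 1240 in the WT libraries at day 0, and at 971 ± 60.6 in KO and 599 and 389 in the WT libraries at day 14. miR-449a-5p had a log2 of 0.39 (adjusted p = 0.533) and miR-34a-5p of -0.06. limma called 8 of 272 small RNAs, 4 each way, and for ribosomal RNA as a class 11 of 12 were higher (camera adjusted p = 0.00598, or adjusted p = 0.222 with an estimated correlation). The miRNA class ranked lower (median log2 -0.04, camera adjusted p = 0.00885, or adjusted p = 0.222 with an estimated correlation). Of the 5 miR-34 and miR-449 rows 3 were lower (adjusted p = 0.00921, or adjusted p = 0.159 with an estimated correlation), and of the 10 reported p53 family targets the same 3 (adjusted p = 0.0179, or adjusted p = 0.467 with an estimated correlation). A test for a genotype difference at any day called 5: miR-34b-3p, miR-34c-5p, miR-34c-3p, miR-125b-1-3p and miR-351-5p. These tests took libraries of different days as independent, although KO libraries of 1 replicate number went together (r = 0.3 to 0.47). With libraries of 1 genotype and number taken as correlated in limma, 4 passed averaged over days (miR-34b-3p, miR-125b-1-3p, miR-351-5p and miR-34c-5p, adjusted p = 0.00762 to 0.0341) and 3 at any day (miR-34b-3p, miR-34c-5p and miR-34c-3p). With 1 mean per genotype and number, 2 against 2, limma called 0, with 19 at an unadjusted p under 0.05 and a smallest adjusted p of 0.231. The averaged count was 14 without WT day 0 replicate 2, 5 without WT day 4 replicate 3 or WT day 14 replicate 2, and 4 without KO day 0 replicate 3, WT day 7 replicate 3, WT day 14 replicate 3 or KO day 14 replicate 3. Without WT day 14 replicate 3 the calls of miR-34c-3p, miR-672-5p, miR-31-5p and Gm25164 were lost (adjusted p 0.0648 to 0.114). miR-449a-5p passed without WT day 0 replicate 2 (0.0209), and library totals gave 8 higher of 12 and upper-quartile factors 3 of 8. The count at any day was 20 without WT day 0 replicate 2, 9 without WT day 0 replicate 3, 3 without WT day 7 replicate 2 or KO day 14 replicate 3, 2 without KO day 0 replicate 2, either WT day 4 library, WT day 7 replicate 3 or WT day 14 replicate 3, and 1 without WT day 14 replicate 2 or KO day 14 replicate 2.

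Whether the change from day 0 differed between genotypes was tested with the interaction of genotype and day. At day 14 miR-34c-5p had the smallest p, with a change in KO lower than in WT by a log2 of -1.74 (SE 0.36, adjusted p = 0.0615 over all small RNAs), followed among its family by miR-34b-3p (-1.84, adjusted p = 0.0968), miR-34c-3p (-2.23, adjusted p = 0.126), miR-449a-5p (-1.87, adjusted p = 0.269) and miR-34a-5p (-0.45, adjusted p = 0.766). Adjusted over the list alone, the first 4 passed in limma (Benjamini-Hochberg adjusted p = 0.00111, 0.0026, 0.0044 and 0.0494). limma called 0 small RNAs at days 4, 7 and 14, with 4, 15 and 49 at an unadjusted p under 0.05. For any day it called 0 of 272, with 20 at an unadjusted p under 0.05. edgeR and limma-voom called 0 in each, and DESeq2 called 0, 0 and 14 and, for any day, 1. With replicate number as a block within genotype, 0, 0 and 15 passed and, for any day, 0. Among the 15 were miR-34c-5p, miR-34b-3p and miR-34c-3p (adjusted p = 0.015, 0.0174 and 0.0229), while miR-449a-5p did not pass. As a class, miRNAs ranked lower in the day 14 interaction (median log2 -0.36, camera adjusted p = 6.11e-07, or adjusted p = 0.0411 with an estimated correlation). For 1 direction fry gave an unadjusted p = 0.0568. Ribosomal RNA (median log2 0.98) and small nucleolar RNA (0.28) ranked higher, each at camera adjusted p = 0.00025. Both were lost with an estimated correlation (adjusted p = 0.0806 and 0.0943). Their unadjusted fry p for 1 direction was 0.0143 and 0.123. At days 4 and 7 too, miRNAs ranked lower in the interaction (median log2 -0.19 and -0.25, camera adjusted p = 0.00011 and 0.000137). With an estimated correlation those calls were lost (adjusted p = 0.0741 and 0.0945). Each interaction subtracts the difference of day 0, where miRNAs ranked higher in KO (median log2 0.14). Without WT day 0 replicate 2, 1, 7 and 12 passed at days 4, 7 and 14 and 3 for any day, and without WT day 0 replicate 3, 1 passed at day 14. The day 14 value of miR-449a-5p was a log2 of -3.14 without WT day 0 replicate 2 and -0.6 without WT day 0 replicate 3.

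Lists fixed beforehand that did not pass in camera in any of 14 comparisons were those of the miR-17-92 clusters of proliferation (smallest adjusted p = 0.107), miR-221 and miR-222 (0.111), let-7 (0.0881), miR-30 (0.168), the miR-23/27/24 clusters (0.0579) and inflammation (0.46). The miR-15/16 (adjusted p = 0.298) and imprinted Dlk1-Dio3 (adjusted p = 0.596) lists had 3 rows for KO against WT at day 0 alone, did not pass there and were not tested elsewhere. The miR-183, miR-96 and miR-182 cluster of sensory epithelia passed in the day 7 interaction alone (median log2 -0.87, adjusted p = 0.0265, or adjusted p = 0.262 with an estimated correlation). The hypoxia list held the 2 arms of miR-210, which fell with time in both genotypes. Too short to test were the mesenchymal list with 2 rows, the neuronal and neuroendocrine list with 2, of which miR-375-3p rose with time, and the miR-29 family, blood cell and Sfmbt2 cluster lists with 1 each. The muscle and endothelium lists had 0 rows.

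The authors' own comparison, deposited beside the values, called 0, 0, 2 and 26 rows at days 0, 4, 7 and 14. Of these, 0, 0, 1 and 8 were also called here. At day 14 the authors' calls comprised 12 higher and 14 lower in KO, and 25 had the same sign here, while 1 of the 26 repeated the values of a named miRNA. For 136 rows of day 7 and 135 of day 14, the authors gave an adjusted p without values in the table of levels.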

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

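The tests of explanations in this part and the counts over other splits were set out after the results they concern were seen, while the interaction tests were planned. The ribosomal RNA test first counted signs over small RNAs (12 of 14 positive in the interaction, exact sign test p = 0.0129) and was then moved to shares per library, because copies of 5S RNA share reads; bounds were also set after the values were known.

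Mature arms of miR-34b and miR-34c differed between genotypes in its change from day 0 to day 14 in the planned interaction test, adjusted over the family: miR-34c-5p by a log2 of -1.74, miR-34b-3p by -1.84 and miR-34c-3p by -2.23, with adjusted p over all small RNAs of 0.0615, 0.0968 and 0.126, or 0.015, 0.0174 and 0.0229 with replicate number as a block within genotype. A lower share of all cells that express the family would lower miR-449 alike if those cells held both at 1 fixed ratio. The log2 ratio of miR-34c-5p to the mean of miR-449a-5p and miR-449c-5p was lower in KO at day 14 by -1.39 (95% interval -2.2 to -0.57, SD pooled over 6 degrees of freedom). This argues against a lower share of such cells as the whole account. At day 0 miR-34c-5p was at 1010 in WT and 1080 in KO, with miR-449a-5p at 7.75 and 20.5. In the WT libraries the log2 ratio was -1.6 and -1.55 at day 4 and -0.49 and -0.53 at day 14. The ratio was therefore not fixed over the days. Whether it changed within cells or with their mix was not measured, and the test reaches neither. Scaling of the libraries is argued against for the difference at day 14 alone, where the smallest of miR-34c-5p over 5 other scalings was -1.27, past the threshold in each; its interaction was -1.83 to -1.13 under them and passed over all small RNAs with TMM factors (adjusted p = 0.044) but not with the other 4. The ratio differed by -0.34 at day 4 (95% interval -1.15 to 0.47) and by -0.95 at day 7 (-1.77 to -0.14). A dependence of miR-34b and miR-34c on p73 itself, in transcription or in later steps that were not measured, stays open as a hypothesis, beside a lower share of cells at a later stage that carry more miR-34 than miR-449, which these libraries of whole cultures do not separate.

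Ribosomal RNA was higher in KO at day 14 by a median log2 of 1.13 over 15 small RNAs, of which 1 was called, and the class call in camera was lost with an estimated correlation (adjusted p = 0.0534). Adjusted over the class alone, 5 of the 15 were higher in limma, though copies of 5S RNA share reads. For ribosomal RNA, fry in 1 direction gave an unadjusted p = 0.00147. A strain difference present at every day is argued against as the whole account by the change of the KO to WT log2 ratio of its share between days 0 and 14, 1.83 (95% interval 0.88 to 2.78, 8 degrees of freedom; 0.67 to 2.99 with replicate number as a block within genotype, 6 degrees of freedom), though pairing the 8 libraries of those days alone gave -0.87 to 4.52 (2 degrees of freedom), which includes 0. The log2 ratio was -0.18 at day 0 (95% interval -0.85 to 0.5), 0.64 at day 4 (-0.03 to 1.32) and 0.66 at day 7 (-0.01 to 1.33), so a difference from day 4 on stays open. Scaling is argued against by the smallest median over 5 other scalings, 1.14. More RNA breakdown in the KO cultures of day 14 may contribute and cannot be told apart from an effect of genotype, since no measure of RNA integrity was used here and the medians of 0.21 for small nucleolar RNAs and 1.08 for 4 small nuclear RNAs, both higher as breakdown would have them, do not decide. Genotype and the state of the cultures stay open.

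miR-449a-5p differed between genotypes in its change from day 0 to day 14 by a log2 of -1.87 (adjusted p = 0.0494 over the list alone and 0.269 over all small RNAs), a value that rests on 7 reads and 1 read in the WT libraries of day 0 and was -3.14 without WT day 0 replicate 2 (adjusted p = 0.00359) and -0.6 without replicate 3 (adjusted p = 0.673). Among lists, the miR-34 and miR-449 family differed in its change to day 7 (median log2 -1.26, camera adjusted p = 0.0038, or adjusted p = 0.109 with an estimated correlation) and to day 14 (median -1.84, adjusted p = 0.000585, or adjusted p = 0.0618). Its only miR-449 row here was miR-449a-5p, so the medians are those of miR-34 rows in the main. miR-449c-5p, too low at day 0 to be tested, did not enter. It went from 7.33 at day 0 to 8620 at day 7 and 5870 at day 14 in WT. In KO it went from 4.19 to 8820 and 4730, with no lag behind WT in that change. The reported p53 family targets differed at day 7 (median -0.42, adjusted p = 0.0186, or adjusted p = 0.262) and day 14 (median -0.46, adjusted p = 0.015, or adjusted p = 0.323). The miR-99, miR-100 and miR-125 family differed at day 4 (median -0.61, adjusted p = 0.0441, or adjusted p = 0.568), day 7 (median -0.6, adjusted p = 0.0228, or adjusted p = 0.519) and day 14 (median -0.83, adjusted p = 0.0284, or adjusted p = 0.583). Each of these subtracts the KO against WT difference of day 0, where this family already ranked higher in KO. That day 0 call was also lost with an estimated correlation. The family did not pass in camera in KO against WT at any later day, which does not show that it was equal there. How far these interactions go beyond the difference of day 0 was not tested. The miR-183, miR-96 and miR-182 cluster differed at day 7 (median -0.87, adjusted p = 0.0265, or adjusted p = 0.262).

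Of 100 splits of the libraries within days, 2 gave as many small RNAs as the 8 of KO against WT averaged over days, the real one included, with 8 as the highest of the others. That excludes chance for the count only if libraries of different days are independent, and the KO libraries of 1 replicate number correlated across days (r = 0.3 to 0.47 across small RNAs, 6 pairs); with 1 mean per genotype and replicate number limma called 0, with 19 at an unadjusted p under 0.05. For a genotype difference at any day, 7 of 100 gave at least the real 5, with 6 as the highest of the others, and chance cannot be excluded. This test is unchanged when the genotypes of a day are swapped whole. A split that only swaps whole days must therefore give the real 5, and the 7 may hold such ties. For genotype by day the real count was 0, so all 100 of 100 splits had to give as many and the count says nothing about chance; the highest of the others was 14 and their median 0.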

How the results depend on the processing

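The alternatives with TMM factors, edgeR, pseudocounts of 0.5 and 5, a minimum value of 50, factors from miRNAs, miRNAs alone, identical rows kept and, for genotype over all days, libraries of 1 genotype and replicate number correlated or averaged were chosen after the values were seen; all others here were planned. Among the small RNAs named, no alternative passed the threshold in the opposite direction. The other small RNAs entered as counts, and their direction was not compared. For the small RNAs named, 3322 alternatives kept the side of the threshold, 36 moved past it and 360 fell short of it. The counts that moved by more than 1.5 times follow as small RNAs past the threshold, KO against WT unless a time course is named. Library totals over days include the rise of miR-92b-3p, which lowers the share of the other small RNAs. Except for this and where fewer small RNAs or libraries enter, the cause was not tested. With 2 libraries per group and as few as 197497 reads, small RNAs under a value of 10 were not tested, which limits miR-449c-5p and miR-34b-5p at day 0.

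With no filter, days 0, 4, 7 and 14 gave 1, 3, 3 and 27, the average 31, WT days 4, 7 and 14 gave 21, 45 and 66, KO days 4 and 7 gave 26 and 59, the interactions of days 7 and 14 gave 1 and 21, genotype by day 13 and genotype at any day 31. DESeq2 gave 0, 3 and 36 at days 4, 7 and 14, 13 averaged, 5 for WT day 4, 14 for the day 14 interaction, 1 for genotype by day and 12 at any day. limma-voom gave 0 at day 4, 56 at day 14, 4 and 12 for WT days 4 and 7 and 3 for KO day 4. edgeR gave 0, 0 and 54 at days 4, 7 and 14, 5 for WT day 4 and 3 for KO day 4. The libraries compared alone gave 0, 0 and 45 at days 4, 7 and 14, 3, 8 and 12 for WT days 4, 7 and 14, and 2 and 14 for KO days 4 and 7. A minimum value of 50 gave 0 at day 4, 7 at day 14, 19 for KO day 7 and 3 for the day 14 interaction, and miRNAs alone gave 0 at day 4 and 1 for the day 14 interaction. A threshold of 0.1 gave 2 and 20 at days 7 and 14, 13 averaged, 15, 54 and 59 for WT, 17 for KO day 4 and 3 for the day 14 interaction. Upper-quartile factors gave 0 at day 7. Library totals gave 0 at day 7, 26 at day 14, 18, 115 and 139 for WT, 58 for KO day 7 and 14 for the day 14 interaction. TMM factors gave 2 at day 7 and 1 for the day 14 interaction, and factors from miRNAs 3 at day 7. The 10 CPM filter, a pseudocount of 5 and the replicate block each gave 2 at day 7, and the block 13 for WT day 4. The block nested in genotype gave 15, 46 and 64 for WT, 17 and 49 for KO days 4 and 7 and 15 for the day 14 interaction. Taking libraries of 1 genotype and replicate number as correlated gave 4 averaged and 3 at any day, and 1 mean of each gave 0 averaged.

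Leaving out 1 library in turn, the lone library being taken to vary like the other groups, gave 0 to 7 at day 0, 0 to 1 at days 4 and 7, 0 to 7 at day 14 and 4 to 14 averaged. It gave 4 to 21, 8 to 34 and 15 to 47 for WT days 4, 7 and 14, 4 to 18, 8 to 25 and 22 to 48 for KO days 4, 7 and 14, 0 to 1, 0 to 7 and 0 to 12 for the interactions, 0 to 3 for genotype by day and 1 to 20 at any day. The highest values of day 0, the average, WT day 4, WT day 7, the interactions, genotype by day and any day were those without WT day 0 replicate 2, and the 0 of day 14 was that without KO day 14 replicate 3.

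Every list call was lost with an estimated correlation: at adjusted p = 0.0628, 0.0548, 0.159, 0.354, 0.0612, 0.109 and 0.0618 for miR-34 and miR-449 at days 7 and 14, averaged, in WT days 7 and 14 and in the interactions of days 7 and 14. For p53 targets it was 0.205, 0.374, 0.467, 0.262 and 0.323 at days 7 and 14, averaged and in the interactions of days 7 and 14. For the miR-99 to miR-125 family it was 0.668 at day 0, 0.587, 0.664 and 0.57 in KO and 0.568, 0.519 and 0.583 in the interactions. For the basal list it was 0.601, for miR-200 0.64 and for the miR-183 cluster 0.262. Of the RNA classes past the threshold in camera, miRNAs kept it in KO day 14 and in the day 14 interaction (0.0235 and 0.0411), and the other class calls were lost at 0.0534 to 0.312. The replicate block gave 0.0531 for the miR-99 to miR-125 family in KO day 4, and the nested block 0.0521 for miR-34 and miR-449 in WT day 7. fry for 1 direction gave 0.424, 0.116, 0.634, 0.399 and 0.232 for the miR-99 to miR-125 family at day 0, KO day 4 and the interactions, 0.768 for the basal list, 0.615 for miR-200, 0.096, 0.159 and 0.0678 for p53 targets at day 7 and in the interactions of days 7 and 14, 0.159 for the miR-183 cluster and 0.0403 for miR-34 and miR-449 in KO day 14. fry for either direction gave 0.841, 1 and 0.305 for the miR-99 to miR-125 family at day 0 and in the interactions of days 4 and 7, 1 for the basal list, miR-200 and the miR-183 cluster, 0.0635 for p53 targets in the day 7 interaction, and 0.00572 and 0.0912 for miR-34 and miR-449 in KO day 14 and the day 7 interaction.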

Other observations

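The observations here are values with no test of an explanation, chosen after they were seen. The small nucleolar RNA Gm26205, in an exon of the ribosomal protein gene Rpl6 annotated as neither coding nor UTR, was at 265 and 311 in the WT libraries of day 7, while the group means were 12.5, 36.4 and 33.6 in WT at days 0, 4 and 14 and 12.8, 42.2, 38.8 and 21.6 in KO at days 0, 4, 7 and 14. miR-449c-5p, next to miR-449a in Cdc20b, was at 7.33, 4840, 8620 and 5870 in WT and at 4.19, 5390, 8820 and 4730 in KO at days 0, 4, 7 and 14.

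miR-92b-3p took 11.69% of the values of KO day 4 replicate 2 and 31.03% of KO day 4 replicate 3, against 24.89% and 32.18% in the WT libraries of that day and 1.11% to 2.3% at day 0. The share of ribosomal RNA was 0.4% and 0.52% in WT and 0.48% and 0.34% in KO at day 0, 0.28% and 0.27% in WT and 0.52% and 0.35% in KO at day 4, and 0.21% and 0.21% in WT and 0.28% and 0.39% in KO at day 7.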
